A study of Mus musculus with 18 samples.

How the data were processed

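The series holds 18 libraries from primary astrocytes of mice homozygous for the R132H point mutation of Eif2b5, a model of vanishing white matter disease. Eif2b5 encodes the catalytic subunit of eIF2B, the exchange factor that recharges the initiation factor eIF2. The cells were cultured for 120 hr in all and were either untreated or given 20 ng/ml TNFα with 0.25 ng/ml IL-1β for the last 24 hr or 48 hr. Each of the 6 groups (RNA-seq or Ribo-seq, untreated, 24 hr or 48 hr) has 3 libraries, from batches A, B and C, which all 6 groups share. Ribo-seq sequences the mRNA fragments that ribosomes protect from nuclease, here of 26 to 34 nt.

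The values analysed were the authors' deposited tables, not reads or counts per library. The main table gives, per the file headers, the log2 fold of treated over untreated cells for 12205 genes in 12 comparisons: mRNA, RPF (ribosome-protected fragments) and RD (ribosome density), at 24 hr and 48 hr, for the mutant and for the WT. How RD was computed is not given in the sources used here, and in the mutant it had a Pearson correlation across genes of 0.93 with the RPF fold minus the mRNA fold at both times. The WT libraries belong to no group of this series, so the WT columns were used only as the authors' comparison. The authors' deposited p-values were signed scores for their 6 gene lists, with no test named. Another table gives the authors' IS value, a score per transcript that the file does not spell out, for mutant cells at 0 hr and 24 hr, with a density signal of elongation reads per transcript, as deposited. Its 2 columns of WT values were not used. The submitters' processing notes name TopHat2, featureCounts and the mouse genome build mm10, with no version given, and the program behind the folds is not given in the sources used here.

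Because the table holds a single pooled fold per gene and comparison, there are no replicate values, no test of any gene was run, and the depth per library is unknown. Genes at or beyond a log2 fold of 1 in either direction were counted as a description. The same holds for the difference of the 48 hr and 24 hr folds, which share their untreated libraries, and for the mutant fold minus the WT fold. The interval given with each median of a gene list is the exact 95% order-statistic interval over its genes. Genes are not independent replicates, so it describes the spread of the members and not the error between cultures. The percentile of each list median was taken among 10000 random lists of the same size from the same column. The files give no expression level, so the random lists were not matched on it.

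Fixed before the data were examined were 34 gene lists, covering NF-kB targets, chemokines, cytokines and growth factors, complement, interferon response, class I antigen presentation, reactive astrocyte genes (pan, A1 and A2), ATF4 targets of the integrated stress response, mRNAs with regulatory upstream reading frames, the unfolded protein response, eIF2 and eIF2B, translation factors, aminoacyl-tRNA synthetases, cytosolic and mitochondrial ribosomal proteins, nuclear and mitochondrial genes of oxidative phosphorylation, cholesterol biosynthesis, cholesterol regulation and transport, fatty acid synthesis, DNA replication, mitosis, apoptosis, extracellular matrix, oxidative stress, and markers of astrocytes, microglia, oligodendrocytes, neurons, endothelium, fibroblasts and mural cells, and ependyma and choroid plexus. The rule for named genes was fixed then too. For each comparison it took the 10 genes with the largest fold in each direction past the threshold and up to 4 members of each list with the largest fold. It added the subunits of eIF2B and a short set of marker genes (Tnf and Il1b among them, for which no fold was analysed here). Predicted gene models were counted and not named.

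Gene names were taken from the symbols in the files, except for 31 symbols damaged by the spreadsheet (19 turned into day numbers), which were replaced through their Ensembl identifiers. A single gene, Dynlt1b, lacked 4 of its mutant folds and was left out of those columns. The mutant RPF folds at 48 hr are deposited with 2 decimals. Coordinates, transcript length and GC content came from GENCODE release M21 on GRCm38, the same assembly as mm10, using for each gene the protein-coding transcript with the longest coding sequence (11992 genes). GC-corrected folds were made by subtracting the median of each of 20 bins of GC content with equal numbers of genes. Matched random lists took each member's GC and length class (5 by 5 classes) into account.

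Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The list procedures were tested on simulated data: lists of 77 genes with no added shift fell between percentiles 24.2 and 80.1, with an added log2 shift of 0.15 between 74.7 and 100, and with 0.3 between 99.9 and 100. Under a simulated GC trend, matched lists placed unshifted lists between percentiles 5.21 and 28.4 and lists shifted by 0.3 at 99.96 or above. The GC correction, tried on the same simulated lists, gave mean recovered shifts of -0.04 and 0.35 over 5 runs each. Alternatives tried were other fold thresholds (0.58 and 1.5), folds centred on the median, list means, the authors' own lists, Spearman correlation and, added after the data were seen, the GC correction, the RPF fold minus the mRNA fold in place of RD, and IS ratios with 0.1 added.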

Results

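The question behind the comparisons was how astrocytes with mutant eIF2B respond to inflammatory cytokines in mRNA level, in ribosome footprints and in ribosome density. Every fold below is treated over untreated cells of the same genotype on the log2 scale. There are no replicate values, so no gene was tested and the folds carry no error. Eif2b5 itself (chromosome 16, 20498817 to 20509323, GRCm38) carries a point change, and its mutant mRNA fold in the authors' deposited table was 0.29 at 24 hr and 0.24 at 48 hr.

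After 24 hr of TNFα and IL-1β, the mutant astrocytes had far more mRNA for chemokines and other inflammatory mediators. In the authors' deposited table the highest mRNA folds were those of Cxcl9, a T-cell attracting chemokine, at 13.97, Ch25h, the cholesterol 25-hydroxylase, at 12.60, Nos2, the inducible nitric oxide synthase, at 12.42, and Csf3, the granulocyte growth factor, at 12.29. The authors' deposited table then gave Saa3 at 11.64, Mmp12 at 11.34, Lilrb4a at 10.72, Cxcl5 at 10.70, Ccl5 at 10.62 and Ccl20 at 10.57. The lowest folds in the authors' deposited table were those of Fgfbp1 at -6.31, Zbbx at -6.07, Adamts18 at -5.71, Oca2 at -5.42 and Sncb at -5.13. Also low in the authors' deposited table were Mip, the lens aquaporin, at -4.53, Cxcr4, a chemokine receptor, at -4.47, Npr3 at -4.36 and Slc39a12 at -4.35. Of 12204 genes, 943 were at or above 1 and 887 at or below -1.

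Immune lists were high as groups in the mutant mRNA at 24 hr. Chemokines had a median fold of 9.31 (interval over genes 5.66 to 10.57), with 14 of 15 members at or above 1. NF-kB targets had a median of 3.16 (2.13 to 4.04), with 24 of 27 at or above 1 and 1 at or below -1. The authors' deposited table gave Tnfrsf9 5.62, Tnfaip2 5.48, Tnfaip3 4.92, Nfkbia, the inhibitor of NF-kB, 3.32, and Sod2, the mitochondrial superoxide dismutase, 3.14. All 39 interferon response genes were at or above 1 (median 3.37, 2.84 to 4.08), among them Gbp5 at 9.29, Zbp1 at 6.98 and Gbp2 at 6.53 in the authors' deposited table. All 19 genes of class I antigen presentation were too (median 3.32, 2.18 to 3.95), and in the authors' deposited table H2-Q6 stood at 6.87, H2-Q7 at 5.52 and the immunoproteasome subunit Psmb8 at 4.31. Each of these 4 medians lay above all 10000 random lists.

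Complement and astrocyte reactivity genes were more mixed at 24 hr. Complement had 7 of 12 members at or above 1 (median 1.39, -0.03 to 4.15), with C3 at 5.82, Cfb at 5.01, C1ra at 4.15 and C1s1 at 4.11 in the authors' deposited table. Cytokines and growth factors had 8 of 19 at or above 1 and 1 at or below -1 (median 0.49, -0.26 to 1.78), and the authors' deposited table gave Il6 6.05, Lif 3.06 and Tgfb3 -2.19. Pan-reactive genes had 8 of 13 at or above 1 and 2 at or below -1 (median 2.13). The authors' deposited table gave Cxcl10 8.74 and Lcn2, the lipocalin that marks reactive astrocytes, 7.79, while the intermediate filament genes Gfap at -1.58 and Vim at -1.27 were lower. The A1 list had 7 of 11 and the A2 list 7 of 12 at or above 1, with medians of 3.40 and 1.38. Apoptosis genes had 4 of 27 at or above 1 and none at or below -1 (median 0.39, 0.12 to 0.67), and the authors' deposited table gave the inflammatory caspase Casp4 5.20, Bid 2.96 and Fas 1.82.

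Cell-cycle genes were lower at 24 hr, and astrocyte markers were mixed. In the mitosis list, 22 of 24 members were at or below -1 (median -1.43, -1.63 to -1.33), with Cenpf at -2.15, Cenpe at -1.90, Anln at -1.82 and Ccnb2 at -1.80 in the authors' deposited table. DNA replication had a median of -0.55 (-0.81 to -0.34), with 4 of 38 at or below -1, and the authors' deposited table gave Pole -1.47 and Mcm10 -1.21. Astrocyte markers had a median of -0.38 (-0.92 to 0.10, percentile 0.16 among random lists), with 4 of 20 at or below -1 and 1 at or above 1. Those with the largest folds in the authors' deposited table were the potassium channel gene Kcnj10 at -2.31, Aldoc at -2.16 and the glutamate transporter gene Slc1a2 at 1.99.

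At 48 hr the mutant mRNA profile largely overlapped that at 24 hr, with 1093 genes at or above 1 and 1006 at or below -1. Of these, 864 and 762 were past the threshold in the same direction at 24 hr, where 84.5 and 73.1 would be shared if the sets were independent. Across 12204 genes the 2 folds had a Pearson correlation of 0.96, though both use the same untreated libraries and genes are not independent replicates. The authors' deposited table had Saa3 highest at 12.36, then Ch25h at 12.32, Nos2 at 11.92, Wfdc17 at 11.10, Lilrb4a at 10.97 and Csf3 at 10.84. At the low end the authors' deposited table had Mip at -6.81, Adamts18 at -6.18, Col8a2 at -5.92, Oca2 at -5.90, Tll2 at -5.84 and Lect1 at -5.73.

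What differed most between the times was the interferon response. All 39 of its genes had a lower mRNA fold at 48 hr than at 24 hr (median difference -0.93, -1.19 to -0.80), 17 of them by 1 or more. Footprints gave the same picture, with 39 of 39 lower and a median difference of -1.01. This was not particular to the mutant. The WT medians of the list were 3.47 at 24 hr and 2.52 at 48 hr in mRNA, and 3.29 and 2.22 in RPF. The differences of the folds for 48 hr and 24 hr in the authors' deposited table were -2.46 for Mx1, -2.32 for Oas3 and -3.86 for the interferon-inducible chemokine Cxcl9. Complement moved the other way, with 10 of 12 members higher at 48 hr (median difference 0.26, 0.05 to 0.53). From the authors' deposited table, the mRNA differences were highest for Adgre1, a macrophage receptor gene, at 5.89, Agtr1b at 3.35 and Wfdc17 at 2.84, and besides Cxcl9 lowest for Lect1 at -3.74, Dkk1 at -2.96 and Ttr at -2.51. In all, 173 mRNA differences and 226 footprint differences were at or beyond 1.

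Footprints followed the mRNA in the mutant. At 24 hr 894 genes had an RPF fold at or above 1 and 964 at or below -1, and at 48 hr 907 and 1012. Of the 943 genes with high mRNA at 24 hr, 802 were also high in footprints, and of the 887 with low mRNA, 746 were low in footprints. Across genes the RPF and mRNA folds had a Pearson correlation of 0.95 and a slope of 0.91 at 24 hr, and 0.93 and 0.87 at 48 hr. The highest RPF folds at 24 hr in the authors' deposited table were those of Acod1, which makes itaconate, at 11.51, Ccl5 at 10.93, Nos2 at 10.39, Vnn3 at 10.33, Madcam1 at 10.20 and Serpina3f at 10.01. The lowest in the authors' deposited table were those of Mip at -7.70, Tll2 at -6.12, Wnt2b at -5.95, Oca2 at -5.42, Adamts18 at -5.21 and Sncb at -5.18. At 48 hr the authors' deposited table had Vnn3 at 11.35, Serpina3f at 10.40, Madcam1 at 10.32 and Saa3 at 10.09 highest, and among the lowest Mip at -7.31, Matn3 at -6.84 and Col8a2 at -6.38. Mitosis genes had median RPF folds of -1.51 at 24 hr and -1.75 at 48 hr, with 22 and 24 of 24 members at or below -1.

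**Figure D1:**
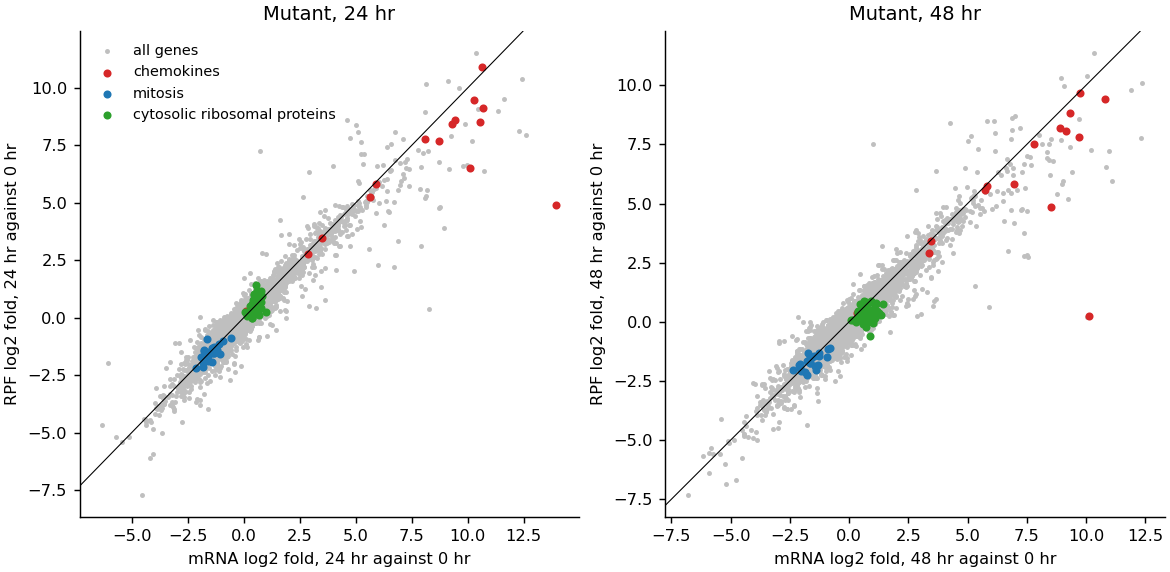
Log2 folds of footprints (RPF, vertical axis) against mRNA (horizontal axis) in mutant astrocytes, at 24 hr on the left and 48 hr on the right, with each point a gene and the line marking equal folds. Chemokines sit at the upper right, with median mRNA and RPF folds of 9.31 and 7.71 at 24 hr, and mitosis genes at the lower left, with -1.43 and -1.51.

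Ribosome density differed at few genes. In the mutant, 74 genes had an RD fold at or above 1 and 134 at or below -1 at 24 hr, and 93 and 151 at 48 hr. With the RPF fold minus the mRNA fold in place of RD, the counts were 54 and 120, and 62 and 165. Several genes with high mRNA folds had low RD folds at 24 hr, which the authors' deposited table gave as -7.14 for Cxcl9, -4.29 for Lamb3, -3.94 for Serpina3c, -3.62 for Lilrb4a, -2.86 for Csf3 and -2.04 for Nos2. Itga9, an integrin gene, had an RD fold of -4.23 with an mRNA fold of -0.43 in the authors' deposited table. Chemokines as a group had a median RD fold of -0.62 (-1.39 to -0.00), with 4 of 15 at or below -1. At the high end, the authors' deposited table gave Zbbx 3.60, the complement factor gene Cfb 3.37, AI607873 3.21, the haem-binding hemopexin gene Hpx 3.19, Fam169a 2.99, Far2 2.79 and the histidine decarboxylase gene Hdc 2.74. At 48 hr the authors' deposited table gave -6.77 for Cxcl9, -4.78 for Serpina3c, -4.41 for Itga9 and -4.06 for Lamb3, and 3.51 for AI607873, 3.14 for Fam169a, 2.80 for Cd72 and 2.79 for Cfb. The 2 times shared 36 of the genes at or above 1 and 78 of those at or below -1. The files give no level, so genes near the detection floor before treatment could not be set apart.

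Genes of the translation machinery were moderately higher in mRNA. All 82 cytosolic ribosomal protein genes had a positive mutant mRNA fold, with a median of 0.48 (0.45 to 0.51) at 24 hr and 0.72 (0.63 to 0.79) at 48 hr, both above all 10000 random lists. Their footprints had medians of 0.50 (0.40 to 0.54) and 0.35 (0.27 to 0.40), and their ribosome density medians of 0.04 (-0.01 to 0.14) and -0.28 (-0.41 to -0.17). At 48 hr the mRNA folds in the authors' deposited table reached 1.42 for Rplp2, 1.37 for Rplp1 and 1.28 for Rpl36, and the RD folds were -1.45 for Fau and -1.21 for Rplp1. Many ribosomal protein genes have processed pseudogenes with which short reads can be shared, so single members are uncertain. Translation factors had median mRNA folds of 0.31 and 0.43 at the 2 times, and the authors' deposited table gave Eif6 1.36 and 1.25 and the elongation factor gene Eef2 0.27 and 0.84. Aminoacyl-tRNA synthetases had medians of 0.38 and 0.32, with Rars at 0.92 and 0.77 in the authors' deposited table. Mitochondrial ribosomal proteins had medians of 0.14 and 0.08.

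Mutant folds of the eIF2B subunit genes were small, while the ATF4 targets of the stress response downstream of eIF2 were mixed. In the authors' deposited table the mutant mRNA folds at 24 hr were 0.26 for Eif2b1, 0.23 for Eif2b2, 0.23 for Eif2b3 and 0.17 for Eif2b4. The eIF2 and eIF2B list had a median of 0.23 (0.17 to 0.35), with the interferon-inducible kinase gene Eif2ak2 at 1.26 in the authors' deposited table. From the authors' deposited table, the mutant-minus-WT RD difference at 48 hr was -1.28 for Eif2b2 and between -0.51 and 0.39 for the other eIF2B subunits. For Eif2b2 the authors' deposited table gave an mRNA difference of 0.78 and an RPF difference of -0.56 at 48 hr. Its RD difference at 24 hr in the authors' deposited table was -0.60. In all, 945 of 12204 genes had an RD difference at or below -1 at 48 hr. ATF4 targets had a median mRNA fold of 0.41 (0.15 to 0.64) at 24 hr and 0.15 (-0.00 to 0.60) at 48 hr, and a median RPF fold of 0.33 (0.08 to 0.49) and -0.04 (-0.27 to 0.26). At 24 hr 5 of 34 were at or above 1 and 4 at or below -1, where 15.0% of all genes were at or beyond 1, and the authors' deposited table gave Slc7a11, the cystine transporter gene, 4.06, Nupr1 3.02, Ddit3 1.17 and Slc7a5 -1.52. The transcription factor gene Atf4 had mutant RPF folds of 0.93 and 0.60 in the authors' deposited table, against 1.77 and 1.03 in the WT. mRNAs with regulatory upstream reading frames had a median mRNA fold of 0.47 (0.23 to 0.85), and the unfolded protein response list 0.20 (0.05 to 0.38), at 24 hr.

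Nuclear oxidative phosphorylation and fatty acid synthesis genes had median mRNA folds near 0, and cholesterol genes were slightly higher at 24 hr. The 77 nuclear genes of oxidative phosphorylation had median mRNA folds of 0.04 (-0.01 to 0.09) and 0.14 (0.02 to 0.21), RPF folds of 0.16 and 0.05, and RD folds of 0.13 (0.05 to 0.23) and -0.04 (-0.11 to 0.01). With folds corrected for GC content, a choice made after the data were seen, both mRNA medians of oxidative phosphorylation were below 0, at -0.014 and -0.0026. The 9 mitochondrially encoded genes had a median RD fold of 0.33 (0.19 to 0.46) at 24 hr and 0.13 at 48 hr. Cholesterol biosynthesis had a median mRNA fold of 0.29 (0.13 to 0.47) at 24 hr and -0.03 (-0.13 to 0.20) at 48 hr, with no member at or beyond 1. The authors' deposited table gave the sterol pathway gene Hmgcs1 0.11 and -0.37. Cholesterol regulation and transport had medians of 0.25 and 0.36, with the oxysterol receptor gene Nr1h3 at 0.57 and 1.00 in the authors' deposited table, and fatty acid synthesis 0.07 and 0.04.

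Markers of other cell types were measured in small numbers. In mutant mRNA at 24 hr, medians were 0.26 for 12 fibroblast and mural markers, 0.12 for 8 oligodendrocyte lineage markers, -0.30 for 7 neuronal, -0.22 for 6 endothelial, -0.91 for 5 ependymal and choroid and 1.00 for 4 microglial and macrophage markers. The authors' deposited table gave Dcn 4.60, Lum 3.47 and Acta2 -2.81 among fibroblast and mural markers, Kdr -3.29 among endothelial, Folr1 -2.41 among choroid and Cd68 1.89 among macrophage markers. At 48 hr the ependymal and choroid median was -2.28, with the choroid plexus gene Ttr at -3.27 in the authors' deposited table. From the authors' deposited table, the folds at the 2 times differed most for Ttr, by -2.51, and next most for Dynlrb2, by -0.54. The lower median thus owed much to Ttr and does not show a like fall of every member.

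**Figure D2:**
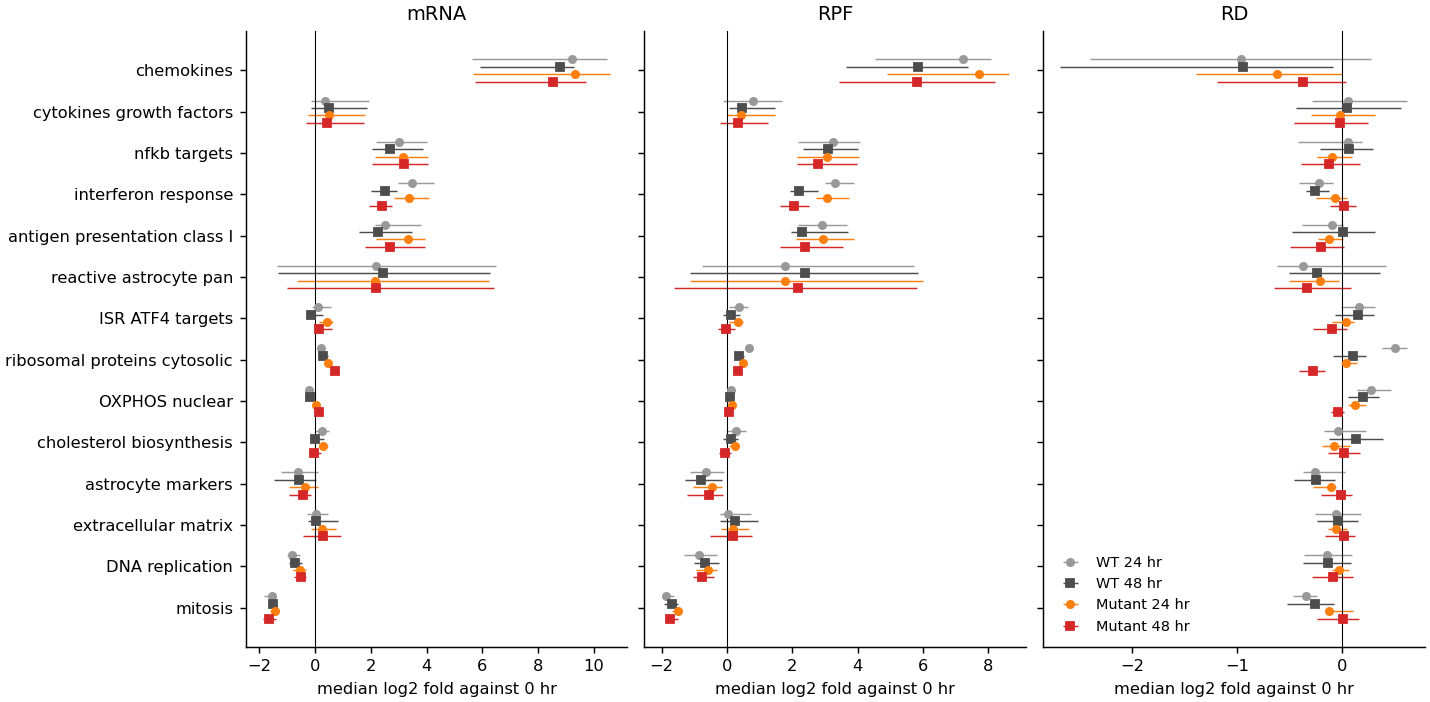
Median log2 folds of 14 fixed gene lists for mRNA, RPF and RD in WT (grey) and mutant (orange and red) astrocytes at 24 hr and 48 hr, with bars for the 95% interval over genes. Medians of the immune lists lie right of 0 in mRNA and RPF in both genotypes and those of mitosis left of 0, while cytosolic ribosomal proteins in RD have mutant medians of 0.04 and -0.28.

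The medians of the inflammatory lists were close in mutant and WT, while single members differed in both directions. Across genes, the mutant and WT folds had Pearson correlations of 0.94 (24 hr) and 0.89 (48 hr) in mRNA and 0.95 and 0.94 in RPF. The rank correlations, which give extreme genes less weight, were 0.82 and 0.63 in mRNA and 0.89 and 0.86 in RPF. The median mutant-minus-WT mRNA difference at 24 hr was 0.16 (-0.11 to 0.33) for chemokines and 0.13 (-0.08 to 0.39) for NF-kB targets, and it was -0.15 (-0.25 to 0.01) for interferon response genes. At 48 hr these medians were -0.10 (-0.23 to 0.55), 0.25 (-0.02 to 0.83) and -0.23 (-0.35 to 0.04). In footprints at 24 hr the chemokine median was 0.03 (-0.34 to 1.06), with 4 of 15 members at or above 1 and 3 at or below -1, and the interferon response median -0.11 (-0.25 to 0.02). The RPF differences from the authors' deposited table at 24 hr and 48 hr were 2.23 and 3.03 for Ccl5, 2.02 and 1.99 for Ccl20, -1.86 and -1.58 for Cxcl9, -1.42 and -2.66 for Oas1a and 1.53 and 1.42 for Traf1. Footprints of cell-cycle genes were less lowered in the mutant at 24 hr, with median differences of 0.33 (0.29 to 0.42) for mitosis, 22 of 24 members being above 0, and 0.27 (0.13 to 0.38) for DNA replication. By 48 hr these medians were 0.07 and -0.01. The WT libraries are not part of this series, and whether they were prepared alongside the mutant ones is not given in the sources used here. A difference between cultures or library sets thus cannot be told from one between genotypes. Replicate values of the mutant alone would not settle this. Lilrb4a and Mmp12 had RPF folds higher by 6.24 and 4.62 in the mutant at 24 hr in the authors' deposited table, and Sdk2 and Il19 had differences of -3.34 and -3.03.

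Ribosome density folds were less alike across all genes. The mutant and WT RD folds had a Pearson correlation of 0.30 at 24 hr and -0.06 at 48 hr across genes (rank correlations 0.23 and -0.22), and 0.45 and 0.26 among genes at or beyond 1 in either genotype. Genes with low RD were still shared, with 52 at or below -1 in both genotypes at 24 hr (1.77 if independent) and 54 at 48 hr (2.59 if independent), while 8 and 10 of the low WT genes were at or above 1 in the mutant. Of the 219 genes with high RD in the WT at 24 hr, 25 were also high in the mutant (1.33 if independent) and 9 were at or below -1. Of the 348 such genes at 48 hr, 21 were high in the mutant (2.65 if independent) and 19 low. At 48 hr 392 genes had a mutant-minus-WT RD difference at or above 1 and 945 at or below -1. The RPF differences past the threshold were 114 and 108, and the mRNA differences 901 and 86. Of the 901 genes with a high mRNA difference, 607 had an RD difference at or below -1. Across genes the mRNA and RD differences at 48 hr had a Pearson correlation of -0.81. RD is close to RPF minus mRNA, so opposite signs are partly built in. Cytosolic ribosomal proteins had a median RD difference of -0.38 (-0.56 to -0.14) at 24 hr and -0.25 (-0.51 to -0.07) at 48 hr. Against random lists matched on GC content and length, a comparison chosen after the data were seen, no list was as low at 24 hr and 55 of 10000 were as low at 48 hr. Their mRNA difference had medians of 0.29 (0.17 to 0.39) and 0.38 (0.24 to 0.63), and their footprint difference -0.17 (-0.26 to -0.07) and -0.04 (-0.12 to 0.03). Nuclear oxidative phosphorylation genes had median RD differences of -0.14 (-0.28 to -0.05) and -0.19 (-0.46 to 0.03), and mitochondrially encoded genes 0.43 (0.31 to 0.71) and 0.84 (0.68 to 1.14).

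The mRNA and RD differences between the genotypes moved with the GC content of the transcript. Across 11991 genes the Spearman correlation of GC content with the mutant-minus-WT mRNA difference was 0.68 at 24 hr and 0.77 at 48 hr, and with the RD difference -0.59 and -0.70. For the RPF difference it was -0.05 and -0.08. In the tenth of genes with the highest GC content, the median mRNA fold at 48 hr was -0.55 in the WT and 0.38 in the mutant, and in the tenth with the lowest it was 0.20 and -0.17. Ribosomal protein transcripts had a median GC content of 51.6% and a median length of 838 nt, against 50.3% and 3130 nt for all genes, and mitochondrially encoded transcripts a GC content of 35.7%.

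**Figure D3:**
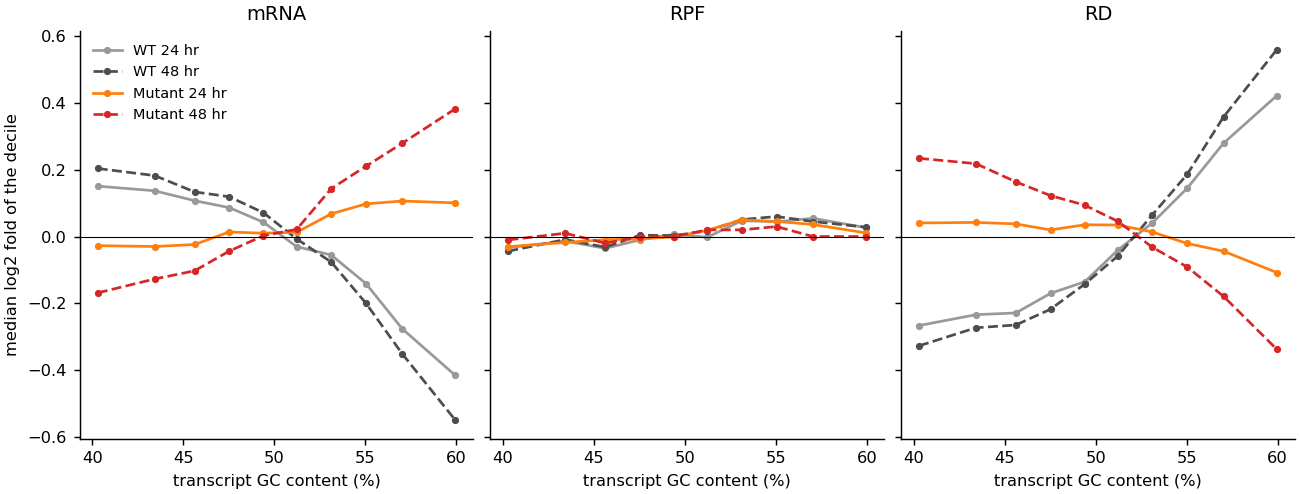
Median log2 folds of genes in 10 classes of transcript GC content (horizontal axis, percent) for mRNA, RPF and RD in WT (grey) and mutant (orange and red) astrocytes at 24 hr (solid) and 48 hr (dashed). In mRNA at 48 hr the class with the highest GC content has a median of -0.55 in the WT and 0.38 in the mutant, while the RPF medians stay near 0.

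The authors' own lists split 3 pathways by the WT ribosome density. Of 77 ribosomal protein genes, 54 had a WT RD fold above 0.3 at 24 hr, and of 75 oxidative phosphorylation genes, 48 were above 0.1. For cholesterol biosynthesis, 9 of 28 genes were above 0.3 at 48 hr. These sections were chosen on the WT folds and are not independent evidence of a difference from the WT. In the mutant, the ribosomal protein section had a median RD fold of 0.03 (-0.01 to 0.13) at 24 hr and -0.39 (-0.49 to -0.22) at 48 hr. The oxidative phosphorylation section had 0.11 (0.03 to 0.25) and -0.09 (-0.23 to 0.01), and the cholesterol section -0.16 (-0.54 to 0.16) and -0.12 (-1.09 to 0.30). The p-value for mutant RD of the ribosomal protein section in the authors' deposited table was 0.30 at 24 hr and 6e-11, with a negative sign, at 48 hr. For cytokine activity the authors' deposited table gave a p of 5e-10 in mutant mRNA at 24 hr, for apoptosis 1e-05 and for DNA replication 6e-06 with a negative sign. Of the authors' 108 p-values, 92 lay within 3 times of a two-sided Mann-Whitney test of the list against all other genes, a test that treats genes as replicates. The other 16 all belonged to the 24 p-values of the ribosomal protein sections, the 6e-11 in the authors' deposited table among them.

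The authors' IS value was lower after 24 hr of treatment in most mutant transcripts. Of 2332 transcripts, 1470 had a lower value at 24 hr, 770 a higher value and 92 were 0 at both times. At 24 hr only, 212 transcripts were 0, against 82 in untreated cells only. Each time has a single pooled value per transcript, with scaling and depth not given in the sources used here. A difference in depth or scaling between the times could therefore not be told from an effect of treatment. The median IS was 2.42 untreated and 1.73 at 24 hr, and over the 1946 transcripts above 0 at both times the median log2 ratio was -0.28 (-0.31 to -0.23). Among 37 transcripts of nuclear oxidative phosphorylation genes the median log2 ratio was -0.86 (-1.18 to -0.57), and among 14 of cytosolic ribosomal proteins -0.49 (-1.33 to -0.15). The authors' deposited table gave IS values of 4.82 and 3.65 for Eef2, 20.2 and 15.3 for Lcn2, 0.34 and 0.92 for C3 and 0.62 and 0.29 for Nfkbia, untreated and at 24 hr. Among the authors' 6 clusters the median log2 ratio ran from -0.38 in cluster 4 (442 transcripts) to -0.12 in cluster 5 (175 transcripts). Across 1910 transcripts, the IS ratio had a Spearman correlation of -0.15 with the mutant RD fold at 24 hr.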

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

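List medians were varied only for cytosolic ribosomal proteins, nuclear oxidative phosphorylation, cholesterol biosynthesis, DNA replication, apoptosis, and cytokines and growth factors. Those of the other lists, among them chemokines, NF-kB targets, interferon response, class I antigen presentation and mitosis, were not varied. Over 85 results and 333 alternative values, 309 stayed within 1.5 times of a count, within the interval of a list median or within 0.1 of a correlation. Of these, 20 lay on the other side of 0 inside an interval that spans 0, so the directions of those medians were not settled. They were 8 for cholesterol biosynthesis, 6 for cytokines and growth factors, 4 for DNA replication and 2 for apoptosis. Medians whose interval excludes 0 were not among them, such as the mutant mRNA medians of DNA replication and apoptosis at 24 hr. The GC correction, the use of RPF minus mRNA in place of RD, the matched random lists and the addition of 0.1 to IS values were chosen after seeing the data. Counts moved with the threshold by construction. At 0.58 they were 3389 and 3937 (RNA, 24 hr and 48 hr), 3427 and 3395 (Ribo), 785 and 1150 (RD) and 638 and 703 (48 hr against 24 hr, RNA and Ribo). At 1.5 they were 1085 and 1204, 1106 and 1164, 90 and 87, and 50 and 71, in the same order. Centring moved the median mRNA fold of ribosomal proteins at 24 hr to 0.45, and the GC correction moved it to 0.45 at 24 hr and 0.62 at 48 hr. That correction also gave the nuclear oxidative phosphorylation list mRNA medians of -0.014 at 24 hr and -0.0026 at 48 hr, both with the sign reversed, and a mutant-minus-WT mRNA difference of 0.13 for ribosomal proteins at 24 hr. By construction these shifts hold the overall median of the folds as well as the GC trend that was removed. In mutant mRNA that overall median was 0.03 at 24 hr and 0.04 at 48 hr. Centring alone thus gave ribosomal proteins the same 0.45 at 24 hr. Spearman's correlation of RNA and Ribo folds at 48 hr was 0.83, and the mean log2 ratio of IS values was -0.35. The cause was not tested for the last 2. No paired analysis was possible because the groups share batches A, B and C but each fold is pooled over libraries. For the same reason the planned runs without a replicate, with a replicate block, with an estimated correlation, with another tool or pseudocount, and with filters or matching on expression level were not run. Centring the IS ratios, which sets their median to 0, and restricting the genotype comparison to genes in every table, which has a single table of folds, were also not run.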

Other observations

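Extracellular matrix and oxidative stress genes were not yet described. In mutant mRNA at 24 hr, extracellular matrix genes went both ways, with 8 of 32 at or above 1 and 6 at or below -1 (median 0.24, -0.16 to 0.76). The authors' deposited table gave the protease genes Mmp3 5.53 and Mmp9 5.25, the proteoglycan gene Dcn 4.60 and the protease inhibitor gene Timp1 2.68, and at 48 hr Postn -3.13. Oxidative stress genes had 5 of 16 at or above 1 and none at or below -1 (median 0.34, 0.00 to 1.33), with Hmox1 at 1.38 and Gsr at 1.33 in the authors' deposited table. In ribosome density, the 16 mRNAs with regulatory upstream reading frames had mutant medians of -0.03 (-0.15 to 0.16) at 24 hr and 0.03 (-0.28 to 0.26) at 48 hr, with none at or beyond 1. Members went both ways, with Cebpb at -0.92 and -0.95, Ddit3 at -0.63 and -0.56 and Atf4 at 0.16 and 0.17 in the authors' deposited table.

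The tests of library yield and of abundance in this first pattern, and the matched lists for ribosomal proteins in the next, were chosen after the result was seen, while the predictions for the others were written before their results. The pattern is that the mutant-minus-WT difference follows transcript GC content in mRNA (rank correlation 0.68 at 24 hr and 0.77 at 48 hr) and inversely in RD (-0.59 and -0.70), and hardly in footprints (-0.0498 and -0.0766). If GC-rich mRNAs had changed in abundance and ribosomes had followed, the footprint slope on GC would share the sign of the mRNA slope, but the ratio of the slopes was -0.0706 and -0.0486. Translation set by the coding sequence alone is argued against by the 3' untranslated region, whose GC content kept a partial rank correlation of -0.22 and -0.34 with the RD difference given that of the coding sequence (-0.33 and -0.40 for the coding sequence given the untranslated region). What remains is consistent with a GC-dependent yield of the RNA-seq libraries that differed between the genotypes' treated and untreated sets, which would enter every RD fold. A change in mRNA level offset by translation in the same GC-dependent way was not tested, and no library value was analysed here that could separate the 2.

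As a list, ribosomal protein mRNAs had a lower median RD difference at 24 hr than random lists matched on GC content and length. It was not seen in the part of the authors' list with low WT RD, given below. Technical explanations stay open at both times, so no biological cause is put forward. At 24 hr the list had a median RD difference of -0.35 over members with a GC value, below all matched random lists (median -0.0240, lower end of the central 95% -0.13, lowest -0.26). At 48 hr it was -0.24 against a median of -0.0630, a lower end of -0.19 and a lowest of -0.34. The trend between the 5 by 5 classes of GC content and length thus gave less than the whole difference at 24 hr and stays open at 48 hr. Matching leaves any trend inside a class. Under the simulated GC trend, unshifted lists fell low, at percentiles 5.21 to 28.4, and no length trend was simulated. A trend inside the classes therefore stays open at both times. Selection on the WT RD alone gave matched lists a median of -0.40 (lower end -0.50, lowest -0.61) against -0.62 for the authors' section at 24 hr. At 48 hr the values were -0.44 (lower end -0.62, lowest -0.82) against -0.67. These lists shared the threshold but were not matched on the level of the WT RD fold, whose median in the section was 0.67 at 24 hr. That level is subtracted in the 24 hr difference, so selection cannot be excluded at either time. The authors' remaining 23 ribosomal protein genes, below the WT threshold, were not lower in the mutant. Their median RD fold less that of all other genes was 0.07 in the WT and 0.13 in the mutant at 24 hr. At 48 hr it was -0.42 and -0.21. These genes were split off by low WT RD, so selection acts on them in the opposite direction. The 20 genes with no pseudogene named after them had medians of -0.42 and -0.31, and the 62 with some -0.38 and -0.21. Pseudogenes under other names were not looked for, so this comparison cannot exclude shared reads. Ribosomal protein genes may vary together, in which case random lists of unrelated genes understate the spread. With no replicate values and with WT libraries from outside this series, a difference between cultures or library sets cannot be told from one between genotypes.

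For nuclear oxidative phosphorylation genes the same tests were less decisive. The median RD difference was -0.14 at 24 hr (matched lists -0.0172, lower end of the central 95% -0.13, lowest -0.24) and -0.19 at 48 hr (matched lists -0.0503, lower end -0.18, lowest -0.33), outside the central 95% but inside the range, so the GC and length trend cannot be told apart from a difference of the list. The authors' section had -0.42 and -0.54, and other genes past the same WT threshold had -0.27 (lower end -0.41, lowest -0.52) and -0.32 (lower end -0.51, lowest -0.72). Genes selected the same way thus had much of the section's difference, and a contribution of the list itself stays open.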
